A study of Homo sapiens with 12 samples.

How the data were processed

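RNA from 4 established human cell lines was measured on Illumina HumanWG-6 v2 bead arrays, with 3 replicate arrays per line and 12 arrays in all. K562 and U937 stain with the antibody 2E9 and are called reactive; HuH-7 and Hutu-80 do not stain and are called non-reactive. The labels do not say whether the replicates of a line were separate cultures, so every p-value below measures only the spread between these samples. The arrays sat on 2 chips, K562 and U937 on one, HuH-7 and Hutu-80 on the other. Chip and reactivity therefore coincide completely, and no fit with chip as a term can separate them. The comparisons of K562 with U937 and of HuH-7 with Hutu-80 each lie within a chip.

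The deposited non-normalized table holds, per the file headers, an average bead intensity per probe and array on a linear scale, exported from BeadStudio 3.0.14 without normalization. It also holds a deposited detection score per probe and array, which the values show to be 1 minus a detection p-value against negative control beads. The authors also deposited a normalized table of intensity on a linear scale, attributed to BeadStudio 2.3.41 in their processing notes, with no method stated. Checked array by array, each of its columns was a straight-line transform of the non-normalized intensity of the same array (r squared 1), that is, background subtracted and rescaled by an array-specific factor. The non-normalized intensities were analysed, and the authors' table served as an alternative.

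The raw table held 48701 probes. Background was corrected with limma's normexp model, using the detection p-values to estimate the background, with an offset of 16. The 14 control probes were then left out, and the remaining 48687 probes were quantile normalized between arrays and put on the log2 scale. Values on this scale are called levels. A probe counted as detected on an array at a detection p of at most 0.01. Probes detected on all 3 arrays of at least 1 line were tested, which left 15933. Symbols came from a probe annotation table; 23675 probes had 1 symbol, 35 had several and 24977 had none. The last 2 kinds were tested but are not named. A gene is represented by its probe with the highest mean level over the 12 arrays, which gave 11462 tested genes out of 18773 on the array. No genome build belongs to the array files, so no positions are given.

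Differences were fitted with limma 3.58.1 in R 4.3.3 as 4 line means with a common spread (8 residual degrees of freedom) and moderated with eBayes using a mean-variance trend. P-values were adjusted by Benjamini-Hochberg over all tested probes within each contrast, and all tests were two-sided. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. The comparison by reactivity used the 4 contrasts of each reactive line with each non-reactive line, and a gene was set apart when all 4 were called in the same direction. The mean of the reactive lines minus the mean of the non-reactive lines was tested as well. The procedure was tested on simulated data with 100 probes changed by 1.5 and 100 by 3 on the log2 scale among 15933. It recovered 100% of them and made 0 false calls. The simulated lines differed only at the changed probes and by the spread between replicate arrays. This result therefore does not bear on false calls for reactivity between real lines, which differ in many genes.

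The 12 arrays had median intensities of 107.9 to 127.6 and 11936 to 13971 detected probes. The median standard error of a difference was 0.0640 for the mean contrast and 0.0905 between 2 lines, on the log2 scale. These errors hold the spread between arrays of a line only. They leave out the spread between lines of the same reactivity, so 0.0640 is not the precision of a comparison by reactivity. Replicate numbers did not pair the arrays of different lines, since the residuals of arrays with the same number had a median correlation across probes of 0.002. No replicate term was therefore used.

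Before the data were examined, 23 gene lists, the rule for naming genes, the comparisons and all alternatives below were fixed. The lists covered γδ T-cell receptor ligands and candidates, the protein C and coagulation surface pathway, adhesion and co-stimulation ligands of T and NK cells, HLA class I and class II presentation, pan-leukocyte, erythroid and megakaryocyte, myeloid and monocyte, and lymphoid markers. They also covered hepatocyte and plasma protein markers, intestinal epithelial markers, epithelial junction and keratin genes, extracellular matrix and mesenchymal genes, integrins and tetraspanins, other cell surface CD molecules, cancer-testis antigens and HOX genes. The remaining lists were interferon-stimulated, cell cycle, cholesterol synthesis, heat shock and stress response, and ribosomal protein genes, and fibroblast and endothelial markers. Each list was tested against all other genes with camera at a preset inter-gene correlation of 0.01 in 3 contrasts (the mean contrast, K562 minus U937, HuH-7 minus Hutu-80), adjusted over all lists and contrasts together.

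For the comparison by reactivity, named genes are the 8 per direction, among genes set apart and detected on all 12 arrays, with the largest smallest difference of the 4. The 6 per direction with the highest level among genes set apart but undetected on every array of the dimmer side, and every measured member of the γδ list, are named too. Within each chip, the 6 per direction with the largest difference among genes detected on all 6 arrays are named, with the 5 per direction that were brightest among genes undetected on every array of the dimmer line. Up to 4 members per list with the largest differences complete the rule. Placeholder symbols, XIST and Y-linked genes were left out. Where a probe was undetected on every array of a group, no fold is given but a bound, written as at least N-fold: the mean level of the brighter arrays against the mean, over the dimmer arrays, of each array's lowest level of any detected probe (or the probe's own level where that is higher). In the comparison by reactivity, the arrays of both lines of a side are averaged. Such a bound then holds for the mean of the lines and not for each line.

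The alternatives were an offset of 50, no background correction with a floor of 16, median scaling, cyclic loess, the authors' table with the same floor, and 3 other detection filters. The setting with an offset of 50 also estimated the background without the detection p-values, so it changed more than the offset. The array medians of the authors' table were 7.3 to 11, so the floor replaced most values of all probes on every array. Further alternatives were the mean of a gene's probes, array weights, no variance trend, a log2 minimum of 2 or none, and a replicate block. Each pair of lines was also fitted alone, and each array was left out. A further 3 fits compared the reactivities with line means, with the line as a random block, or with the 6 arrays of a reactivity as the unit. The 2 other ways of splitting the 4 lines, an estimated inter-gene correlation for camera and the self-contained test fry completed the alternatives. Other packages were statmod 1.5.0, and Python 3.11.15 with matplotlib 3.10.9 for the plots.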

Results

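Gene expression was profiled in 4 human tumour lines on 12 arrays, 3 per line. K562, an erythroleukemia line, and U937, a myelomonocytic line, stain with the antibody 2E9; HuH-7, a hepatoma line, and Hutu-80, a duodenal carcinoma line, do not. The antibody 2E9 prevents the γδ T-cell clone LES from recognising its target cells and binds to those targets. Between 11936 and 13971 probes per array were detected, and the median intensity per array lay between 107.9 and 127.6. Levels correlated across probes with r of 0.996 to 0.998 between arrays of the same line and 0.701 to 0.803 between arrays of different lines.

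The comparison of the 2 reactive lines with the 2 non-reactive lines asked which transcripts follow 2E9 staining, as one encoding the ligand of the LES receptor should. Transcripts of PROCR, the endothelial protein C receptor, which the study's publication names as a γδ receptor ligand, were present in both reactive lines and undetected in both non-reactive lines. The PROCR level (probe ILMN_1717262) was 8.95 ± 0.14 in K562 and 9.95 ± 0.11 in U937 (mean ± SD, n = 3 arrays each, log2 scale), and the probe was detected on 6 of 6 reactive arrays. In HuH-7 it was 4.997 ± 0.09 and in Hutu-80 5.18 ± 0.07, undetected on 6 of 6 non-reactive arrays. PROCR was at least 11.4-fold higher in the mean of the reactive lines (adjusted p = 6.55e-21, limma).

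Among the other γδ receptor ligands and candidates, MR1, which presents vitamin B metabolites to T cells, showed the same pattern. Its level was 9.33 ± 0.06 in K562 and 9.29 ± 0.11 in U937, and it was undetected on all 6 non-reactive arrays. It was at least 10.4-fold higher in the mean of the reactive lines (adjusted p = 9.74e-19). MICB, a stress-induced ligand of NKG2D, was detected everywhere and was 2.32-fold higher in the mean of the reactive lines and 2.12-fold higher in the smallest of the 4 contrasts. Its call over all 4 contrasts was lost with an offset of 50, without background correction, with median scaling and with a log2 minimum of 2. Its call in a single contrast of reactivity was lost with the line as a random block and with line means. EPHA2, an ephrin receptor, went the other way. It was detected at 10.20 ± 0.06 in HuH-7 and 11.17 ± 0.04 in Hutu-80, undetected in both reactive lines, and at least 23.1-fold lower there (adjusted p = 1.70e-23).

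No other measured member of that list was set apart in all 4 contrasts. HLA-B was bright in U937 (12.74 ± 0.06), lower in Hutu-80 (7.60 ± 0.06) and undetected in K562 and HuH-7. HLA-C, CD1D and ULBP1 were higher in the mean of the reactive lines, with U937 the brightest line, at 9.28 ± 0.05, 8.02 ± 0.13 and 7.23 ± 0.13. BTN3A2, a butyrophilin, stood between 8.42 and 8.57 in K562, U937 and HuH-7 and was undetected in Hutu-80. MICA was lowest in HuH-7, at 6.56, and highest in Hutu-80, at 10.45 ± 0.15. APOA1 was detected in HuH-7 alone, at 15.07 ± 0.09. ANXA2 was lower in the mean of the reactive lines (log2 difference -1.51 ± 0.04, SE; -2.11 at its other probe). BTNL9, undetected in U937 and HuH-7, was called lower in that mean by the narrowest margin, and lost the call without K562 replicate 3 or without U937 replicate 3.

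The remaining members measured did not reach the 2-fold minimum in the mean contrast. BTN2A1 (log2 difference 0.04), ATP5F1A (0.04), HSPD1 (0.00) and ATP5F1B (-0.10) were nearly level in that contrast, as was CD1C (0.24). HSPA9 (0.27), HLA-E (0.39), B2M (0.74) and MICA (0.91) were higher by less than 2-fold. BTN2A2, BTN3A3, ULBP2, BTN3A1 and HLA-G were undetected on some arrays and were not called. Of the 41 members, 37 were on the array and 26 were tested: 8 higher, 4 lower and 14 not called in the mean contrast, with the same counts when adjusted over the list alone. As a list they were not shifted against other genes (adjusted p = 0.0666).

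**Figure D1:**
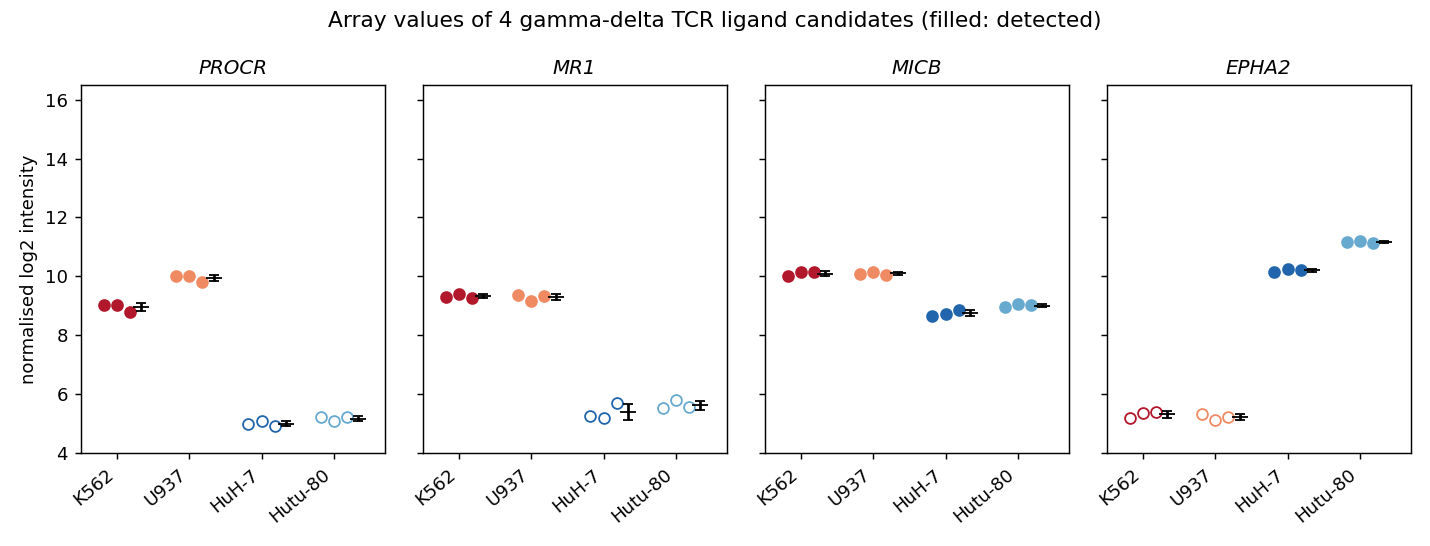
Normalised log2 intensity of PROCR, MR1, MICB and EPHA2 in the 4 lines; each circle is 1 array, 3 per line, filled where the probe was detected and open where it was not, and the black marks beside them give the mean and SD of the line. PROCR and MR1 were detected on all 6 reactive arrays (K562, U937) and on none of the 6 non-reactive arrays, EPHA2 the reverse, and MICB on all 12.

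Over all genes, 290 were higher in both reactive lines than in both non-reactive lines and 426 were lower, out of 11462 tested. The genes detected on all 12 arrays with the widest separation upward were led by WAS, the actin regulator of blood cells, which was 90.4-fold higher in the mean of the reactive lines and 54.4-fold in the smallest of the 4 contrasts. MYB, a transcription factor of blood progenitors, was 52.2-fold higher, and TIMP1, an inhibitor of matrix metalloproteinases, 32.6-fold. FUT4, a fucosyltransferase, was 18.9-fold higher by its brightest probe; its other probe was detected in U937 alone. FBXO6, an F-box protein, was 7.52-fold higher. The RNAs RN7SK, RNU11 and SCARNA9, which act in transcription control, minor splicing and Cajal bodies, were 25.9-fold, 17.9-fold and 18.9-fold higher. RN7SK also varied most between arrays of a line among these genes, at 10.47 ± 0.58 in K562. It lost its call in the single contrast of reactivity fitted with the line as a random block.

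Other genes were detected on every reactive array and on no non-reactive array. PRKCB, a protein kinase C, was at least 111-fold higher, RAC2, a GTPase of blood cells, at least 89.5-fold, and MS4A3, a membrane protein of myeloid cells, at least 88.6-fold; at other probes PRKCB was at least 28.3-fold and 28.7-fold higher and MS4A3 at least 21.2-fold. The actin regulator GMFG was at least 59.1-fold higher, cyclin D2 (CCND2) at least 42.8-fold, and the tumour necrosis factor receptor TNFRSF1B, a surface protein, at least 38.2-fold. Downward, the nuclear receptor NR2F1 was 28.7-fold lower in the mean of the reactive lines and 11.2-fold lower in the smallest contrast. ID2, an inhibitor of helix-loop-helix factors, was 23.4-fold lower, the tropomyosin TPM2 16.1-fold (log2 difference -4.43 at 1 other probe, and at least 1.79-fold lower at another), the tubulin TUBB3 15.4-fold, the tight junction protein CGN 14.3-fold and TRNP1 14.2-fold. The surface proteoglycan SDC1 was 10.4-fold lower and the protease CTSV 7.93-fold.

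Genes present in both non-reactive lines and undetected in both reactive lines included DKK1, a secreted Wnt inhibitor, at least 329-fold lower in the reactive lines. UCHL1, a ubiquitin hydrolase, was at least 242-fold lower, the collagen COL5A2 at least 182-fold and the calponin CNN3 at least 116-fold. YAP1, the transcriptional coactivator of the Hippo pathway, was at least 111-fold lower and the profilin PFN2 at least 70.6-fold by its brightest probe, and at least 4.40-fold by its other probe. Of the 290 genes set apart upward, 105 were undetected on every non-reactive array. Of the 426 set apart downward, 233 were undetected on every reactive array.

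By list, leukocyte, myeloid and erythroid markers were higher in the mean contrast, and epithelial, hepatocyte, intestinal and matrix genes lower. Pan-leukocyte markers had 34 of 39 tested members higher in the mean contrast and 0 lower, and 20 were set apart in all 4 contrasts (adjusted p = 1.04e-12). Myeloid and monocyte markers had 30 of 37 higher and 2 lower, with 5 set apart upward (adjusted p = 6.25e-09), including the microglial and macrophage marker AIF1, at least 42.2-fold (at least 11.02-fold at its other probe), and the myeloid transcription factor SPI1, at least 20.7-fold. Erythroid and megakaryocyte markers had 28 of 40 higher and 2 lower, with 6 set apart upward (adjusted p = 6.87e-08), including the transcription factor NFE2, at least 34.2-fold, and the Kell-linked membrane protein XK, at least 28.4-fold. HLA class I presentation genes had 4 of 13 higher, namely PSMB8, HLA-B, TAP2 and HLA-C, and 0 lower, and were shifted upward (adjusted p = 0.000963); none was set apart in all 4 contrasts, and the 2 TAP2 probes differed in sign.

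Epithelial junction and keratin genes were lower in the reactive lines, with 23 of 34 lower, 1 higher and 9 set apart downward (adjusted p = 9.36e-09). The tight junction protein CLDN1 was at least 60.8-fold lower and N-cadherin (CDH2) at least 56.5-fold. Extracellular matrix and mesenchymal genes had 33 of 52 lower and 8 higher, with 15 set apart downward and TIMP1 upward (adjusted p = 4.19e-06); the matricellular growth factor CCN2 was at least 164-fold lower. Hepatocyte and plasma protein markers had 64 of 75 lower and 2 higher (adjusted p = 1.25e-16), with 3 set apart downward, namely GPC3, FOXA1 and ANG. The proteoglycan GPC3 was at least 44.0-fold lower. Intestinal epithelial markers had 17 of 25 lower and 4 higher, with 2 set apart downward and 1 upward (adjusted p = 0.000214), among them the intestinal transcription factor CDX2, at least 15.8-fold lower. HOX genes had 10 of 19 lower and 1 higher (adjusted p = 0.0123); this call was lost with an estimated correlation (adjusted p = 0.0673). The other shifts named in this and the preceding paragraph held with an estimated correlation.

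The other lists were not shifted in the mean contrast. Other cell surface CD molecules had 43 of 117 higher and 28 lower (adjusted p = 0.116), with 11 set apart upward and 8 downward. Of the higher members, BST2 (tetherin) was detected in both reactive lines and on 3 of 6 non-reactive arrays, and the early activation antigen CD69 was at least 10.7-fold higher. Interferon-stimulated genes had 8 of 34 higher and 3 lower (adjusted p = 0.0874), including IFITM1, at least 19.4-fold higher, and IFITM3, at least 6.55-fold lower. HLA class II presentation genes had 3 of 7 higher (adjusted p = 0.0779). Adhesion and co-stimulation ligands had 8 of 19 higher and 4 lower (adjusted p = 0.182), among them CD47, an inhibitor of phagocytosis, detected in both reactive lines and on 3 of 6 non-reactive arrays. Integrins and tetraspanins had 8 of 35 higher and 14 lower (adjusted p = 0.237), and cancer-testis antigens 10 of 20 higher and 5 lower (adjusted p = 0.199).

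The protein C and coagulation surface list, which holds PROCR, had 5 of 20 members higher and 7 lower (adjusted p = 0.898). PROCR and the urokinase receptor PLAUR, chosen for mention after its values were seen, were set apart upward. Lymphoid markers had 2 of 6 higher and 1 lower (adjusted p = 0.654), and fibroblast and endothelial markers 4 of 11 higher and 5 lower (adjusted p = 0.394). Cell cycle genes had 1 of 55 higher and 1 lower (adjusted p = 0.872), cholesterol synthesis genes 1 of 20 higher and 1 lower (adjusted p = 0.341), and heat shock and stress genes 6 of 44 higher and 4 lower (adjusted p = 0.480). HMOX1, heme oxygenase, was lower in the reactive lines and undetected in K562. Ribosomal protein genes had 0 of 48 higher and 1 lower, RPL37 (adjusted p = 1.00).

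**Figure D2:**
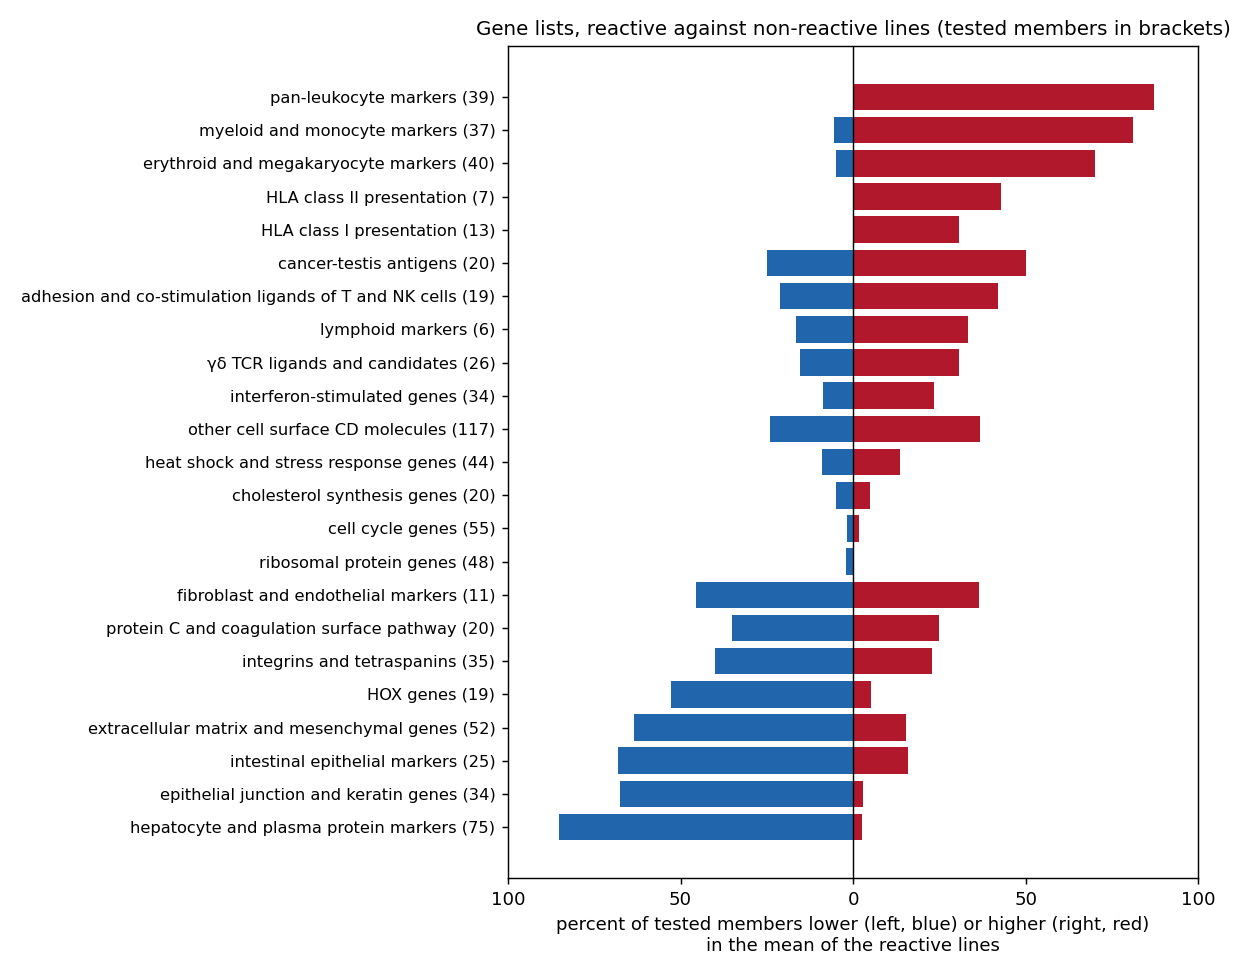
Percent of the tested members of each of the 23 gene lists (number tested in brackets) called higher (red, right) or lower (blue, left) in the mean of the reactive lines than in the mean of the non-reactive lines. Leukocyte, myeloid and erythroid markers lay mostly on the higher side, and hepatocyte, epithelial, intestinal and matrix genes mostly on the lower side.

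In the mean contrast, 1581 genes were higher and 1964 lower. Chip and reactivity coincide, so neither count separates a difference between the chips from a difference between the lines. These p-values rest on the spread between arrays of a line. With each line reduced to its mean, 2 lines against 2, limma called 0 genes (PROCR: unadjusted p = 0.00166, adjusted p = 0.252). There 738 of 11462 tested genes had an unadjusted limma p under 0.05, and many genes would pass that threshold without any difference.

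K562 and U937 were compared within their chip, to see how far the 2 reactive lines differ. Erythroid genes were higher in K562, and granulocyte and monocyte genes in U937. HBZ, the embryonic zeta globin, was at least 684-fold higher in K562, where its level was 15.48 ± 0.14 (SD, n = 3). The globin genes HBG1, HBG2 and HBA1 were at least 622-fold, 596-fold and 493-fold higher, although probes of these duplicated genes cannot be assigned to a single copy with certainty. The tumour antigen PRAME was at least 296-fold higher in K562, and at least 12.04-fold at its other probe. Among genes detected in both lines, the small noncoding RNA SNAR-A1, of a duplicated family, was 71.5-fold higher in K562, MLLT11 68.5-fold and the actin bundler FSCN1 67.3-fold. The platelet glycoprotein GP1BB was 61.5-fold higher, SAMSN1 56.8-fold and RFESD 50.6-fold.

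U937 was brighter for the neutrophil proteases CTSG and ELANE, at least 505-fold and 420-fold lower in K562. CST7, a cystatin, was at least 337-fold lower in K562, the leukocyte integrin chain ITGB2 at least 294-fold and the chemokine receptor CXCR4 at least 266-fold (at least 32.4-fold at its other probe). CD93, a myeloid and endothelial surface protein, was detected in both lines and was 229-fold higher in U937. RASSF2 was 82.6-fold higher in U937, the adhesion adaptor LPXN 71.6-fold and GPNMB 60.3-fold. The myeloid transcription factors GFI1 and CEBPA were 53.3-fold and 51.5-fold higher in U937. In all, 1808 genes were higher in K562 and 2195 were lower. PROCR was lower in K562 than in U937, with a log2 difference of -1.004 ± 0.11 (SE).

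By list, erythroid and megakaryocyte markers had 31 of 40 higher in K562 and 2 lower (adjusted p = 6.49e-09). Cancer-testis antigens had 14 of 20 higher and 0 lower (adjusted p = 1.15e-05), and epithelial junction and keratin genes 14 of 34 higher and 0 lower (adjusted p = 3.53e-05), with KRT18 at least 130-fold (at least 5.67-fold and 6.90-fold at its other probes) and EPCAM at least 73.7-fold. Myeloid and monocyte markers had 32 of 37 lower in K562 and 1 higher (adjusted p = 3.02e-11), and pan-leukocyte markers 31 of 39 lower and 2 higher (adjusted p = 6.25e-09), with the coronin CORO1A at least 171-fold lower. HLA class I presentation genes had 10 of 13 lower in K562 and 0 higher (adjusted p = 0.000720), with HLA-B at least 89.8-fold lower. By its brightest and other probe, PSMB8 had log2 differences of -6.73 and -5.94, TAPBP -1.86 and -0.57, and TAP2 -1.14 and 0.02. The calls of TAPBP and TAP2 thus rest on the brightest probe. Interferon-stimulated genes had 18 of 34 lower and 5 higher (adjusted p = 0.00369), and other CD molecules 52 of 117 lower and 14 higher (adjusted p = 0.00387), with the hyaluronan receptor CD44 at least 89.6-fold lower (at least 1.35-fold at its other probe).

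HLA class II presentation genes had 5 of 7 lower in K562 (adjusted p = 0.0268; adjusted p = 0.248 with an estimated correlation, so the call was lost). Heat shock and stress genes had 13 of 44 higher and 3 lower (adjusted p = 0.0211; adjusted p = 0.303 with an estimated correlation, so the call was lost). The other shifts between K562 and U937 held. HOX genes had 10 of 19 higher in K562 and 4 lower without a list shift (adjusted p = 0.161), HOXB9 being at least 108-fold higher. In the protein C list, tissue factor pathway inhibitor (TFPI) was at least 264-fold higher in K562, and at least 130-fold and 39.9-fold at its other probes.

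HuH-7 and Hutu-80 were compared within the other chip. Hepatocyte and plasma protein genes were higher in HuH-7. Transferrin (TF) was at least 778-fold higher in HuH-7, where its level was 15.65 ± 0.04 (SD, n = 3), and alpha-fetoprotein (AFP) at least 645-fold. The plasma protein precursor AMBP was at least 637-fold higher, the trypsin inhibitor SPINK1 at least 597-fold and the apolipoprotein APOA2 at least 587-fold. Among genes detected in both lines, SERPINA1, the alpha-1 antitrypsin gene, was 491-fold higher in HuH-7 and the asialoglycoprotein receptor ASGR1 91.5-fold. The keratin KRT8 was 79.6-fold higher, the sulfotransferase CHST13 78.2-fold, the caldesmon CALD1 77.6-fold and the liver transcription factor FOXA3 69.5-fold. These are the values of the brightest probes; at their other probes SERPINA1 was at least 2.41-fold and CALD1 at least 2.23-fold higher.

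Hutu-80 was brighter for GCG, the proglucagon gene of gut endocrine and pancreatic alpha cells, which was at least 728-fold lower in HuH-7. The glucose transporter SLC2A3 was at least 536-fold lower in HuH-7 and lactate dehydrogenase B (LDHB) at least 381-fold; both were detected on every array of the other 3 lines. The homeobox gene LHX2 was at least 342-fold lower in HuH-7 and the kinesin KIF1A at least 327-fold. The elongation factor EEF1A2 was 266-fold higher in Hutu-80, the proteoglycan LUM 245-fold, CAVIN2 122-fold, the troponin TNNT1 92.3-fold, the RNA sensor IFIH1 81.5-fold and the semaphorin SEMA3C 71.5-fold. In all, 2058 genes were higher in HuH-7 and 1914 were lower. PROCR was undetected in both lines.

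By list, hepatocyte and plasma protein markers had 72 of 75 higher in HuH-7 and 0 lower (adjusted p = 1.48e-25). Intestinal epithelial markers had 21 of 25 higher in HuH-7 and 1 lower (adjusted p = 9.36e-09), although Hutu-80 is the line of intestinal origin. TSPAN8 was at least 130-fold higher in HuH-7, the fatty acid binding protein FABP1 at least 168-fold and the cadherin CDH17 at least 135-fold. Epithelial junction and keratin genes had 16 of 34 higher and 4 lower (adjusted p = 0.0144), and other CD molecules 36 of 117 higher and 11 lower (adjusted p = 0.00369). Cholesterol synthesis genes had 8 of 20 higher in HuH-7 and 0 lower (adjusted p = 0.00252), HMGCS1 with a log2 difference of 2.73. HOX genes had 12 of 19 lower in HuH-7 and 2 higher (adjusted p = 0.00414), with HOXB8 at least 73.5-fold and HOXB5 at least 78.7-fold lower.

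These list shifts held with an estimated correlation, and the following were lost. The protein C list had 10 of 20 higher in HuH-7 and 2 lower (adjusted p = 0.0238; adjusted p = 0.0877 with an estimated correlation). Myeloid and monocyte markers had 8 of 37 higher and 0 lower (adjusted p = 0.0198; adjusted p = 0.124 with an estimated correlation), including lysozyme (LYZ), at least 96.9-fold. Interferon-stimulated genes had 13 of 34 higher and 4 lower (adjusted p = 0.0344; adjusted p = 0.0659 with an estimated correlation). Lists not named for these pairs of lines were not shifted. Within every list, the counts adjusted over the list alone equalled those over all genes tested. Median, mean and test direction differed in sign for some uncalled shifts: the protein C and ribosomal lists in the mean contrast, those and the γδ list in K562 against U937, and the γδ, leukocyte, erythroid, lymphoid, matrix and cancer-testis lists in HuH-7 against Hutu-80.

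**Figure D3:**
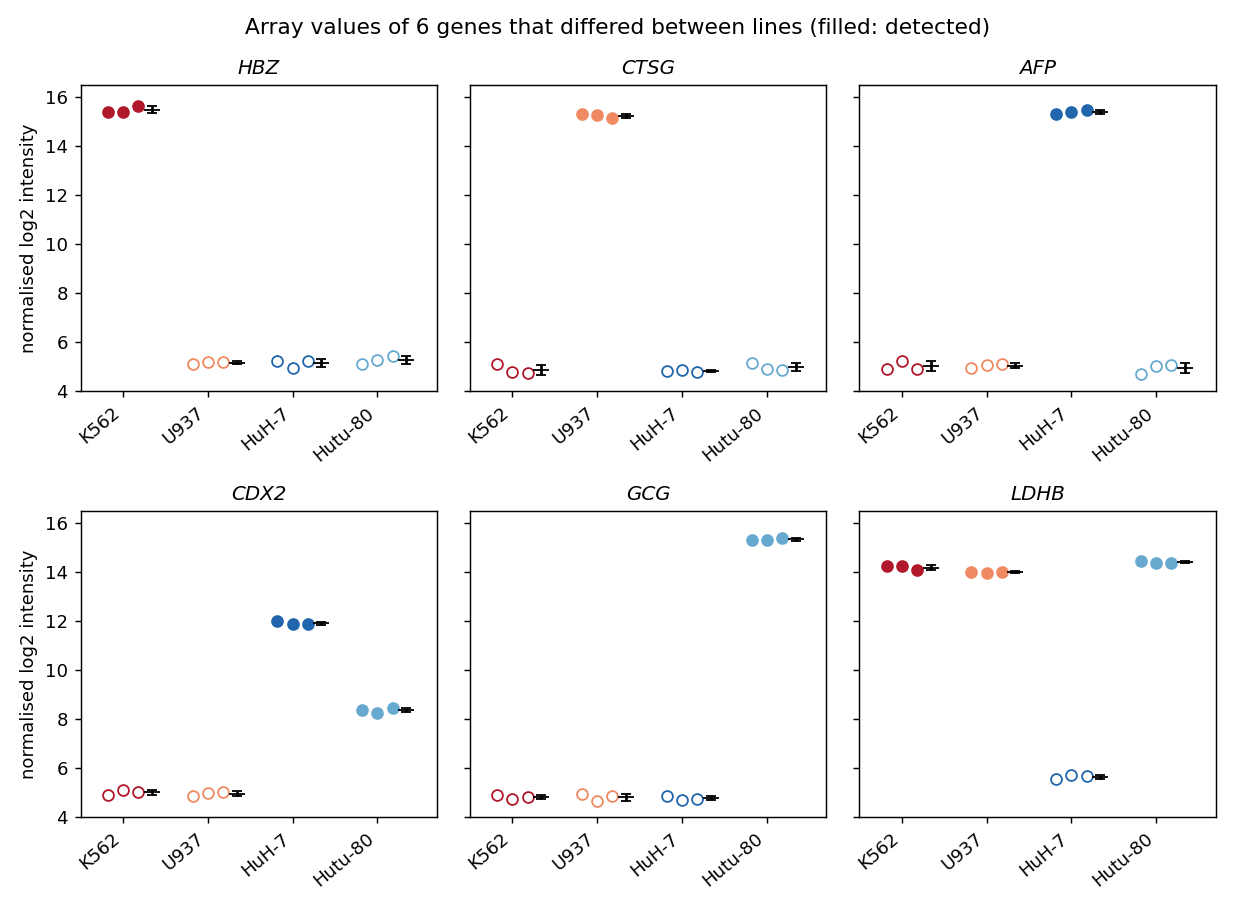
Normalised log2 intensity of HBZ, CTSG, AFP, CDX2, GCG and LDHB in the 4 lines; each circle is 1 array, 3 per line, filled where the probe was detected and open where it was not, and the black marks beside them give the mean and SD of the line. HBZ was detected in K562 alone, CTSG in U937 alone, AFP in HuH-7 alone and GCG in Hutu-80 alone, CDX2 was brighter in HuH-7 than in Hutu-80, and LDHB was undetected in HuH-7 alone.

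The 4 pairs across reactivity differed in 3433 to 4829 genes, against 4003 between K562 and U937 and 3972 between HuH-7 and Hutu-80. The line means of K562 and Hutu-80 were the most alike (r across probes 0.804) and those of U937 and HuH-7 the least (r 0.704).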

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

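All alternatives reported here were planned before the data were examined. No count moved by more than 1.5 times under an offset of 50, median scaling, cyclic loess, the authors' table, no filter or a detection p of 0.05, the mean of a gene's probes, array weights, no variance trend, a replicate block or pairs of lines fitted alone. The authors' table, with values under 16 raised to 16, shared 289 of the 290 genes set apart upward and 409 of the 426 downward. Its median gene lay 0.13 higher in K562 minus HuH-7, against 0.05 as processed here. The replicate block shared all 290 and all 426. Leaving out 1 array at a time gave 284 to 295 genes set apart upward and 423 to 432 downward. In the same way the mean contrast gave 1575 to 1593 higher and 1961 to 1980 lower, K562 against U937 1793 to 1826 and 2183 to 2204, and HuH-7 against Hutu-80 2049 to 2066 and 1901 to 1938. Chip as a block could not be fitted and was not run, since chip and reactivity coincide.

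The counts below are given in the order set apart upward and downward, mean contrast higher and lower, K562 higher and lower than U937, HuH-7 higher and lower than Hutu-80. Detection on all 12 arrays, which removes every gene silent in a line, gave 107, 86, 603, 462, 901, 930, 677 and 945, and 11 list shifts in place of 28. A log2 minimum of 2 gave 117, 199, 516, 856, 755, 1075, 1090 and 667, and the adjusted p alone gave 1417, 1337, 5066, 4969, 4448, 4457, 4104 and 5095; both follow from the size demanded. Without background correction, which compresses differences of dim probes, 186 and 274 genes were set apart, 1000 were higher in the mean contrast and 1273 lower in HuH-7 than in Hutu-80. With line means as the unit, limma gave 0, 0, 0 and 0 for the first 4 counts. There 738 of 11462 tested genes had an unadjusted p under 0.05, the smallest adjusted p was 0.121, and fewer samples were fitted. With the line as a random block (consensus correlation 0.967) they were 154, 233, 176 and 260, with 1886 genes at an unadjusted p under 0.05. With 6 arrays against 6 and the line ignored, the mean contrast gave 860 higher and 1011 lower. Splitting the lines as K562 and HuH-7 against the others set apart 213 and 229 genes, and as K562 and Hutu-80 against the others 191 and 304. With fry, 68 list shifts were called, because it tests whether a list moves at all; an estimated correlation kept 22.

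In the mean contrast PROCR kept its call in 27 of 28 settings; the size of its difference is not compared between settings, because the non-reactive arrays lie at background. It lost the call with line means alone (adjusted p = 0.252), where the line is the unit. With the line as a random block its adjusted p was 0.00135. The residual degrees of freedom of that fit counted arrays, although each line has a single reactivity. This smaller p-value is therefore no evidence at the level of lines. MR1 and EPHA2 lost their calls in the mean contrast with line means alone. MICB lost its call there with line means, with the line as a random block and with a log2 minimum of 2; over all 4 contrasts it also lost it with an offset of 50, with median scaling and without background correction. In the mean contrast, TAP2 changed sign and lost its call with the mean of a gene's probes (fitted value -0.0448), because its 2 probes differ in sign. CD79A, detected in U937 alone, lost its call without U937 replicate 3 or Hutu-80 replicate 3. HLA-DRB1, also detected in U937 alone, passed the 2-fold minimum without K562 replicate 1, U937 replicate 2, Hutu-80 replicate 2 or Hutu-80 replicate 3, and RPL13 without K562 replicate 3 (-1.002). In K562 minus U937, RPL32 passed it without U937 replicate 1 (1.04) or replicate 3 (1.02). For the 32 genes followed over all 4 contrasts, which are the genes named for the widest separation and PROCR, MR1, MICB and EPHA2, 907 of 945 values kept their direction and call and 38 lost the call: 32 with line means, 2 with the line as a random block (RN7SK and MICB) and the other 4 MICB. For up to 4 genes per list and the γδ list, 2765 of 2992 mean-contrast values stayed called or uncalled. Calls were lost in 195, gained in 31, reversed in 1. K562 minus U937 kept 2573 of 2598, HuH-7 minus Hutu-80 2713 of 2728. Signal over background limits the folds: the lowest detected level per array lay between 5.76 and 6.39, and no difference below it can be seen.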

Other observations

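The random assignments of arrays, the splits of 3 arrays against 3 and the counts for the other 2 ways of splitting the lines were planned, the last without a prediction written beforehand; all other tests in this part, and the genes and gene classes named here outside the fixed lists, were chosen after related results had been seen.

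Hutu-80 expressed several regulators of endocrine cells beside GCG. PAX6 had a level of 12.31 in Hutu-80 and 6.999 in HuH-7, and NKX2-2 (10.58), ISL1 (10.31) and the neuroendocrine secretory protein VGF (10.29) were higher in Hutu-80 as well. HuH-7 was higher for other genes of endocrine cells, among them the peptidase CPE (10.52), the neuropeptide precursor NTS (12.59) and the transcription factor RFX6 (7.29). K562 also carried NKX2-2, at 9.58, and VGF, at 9.44.

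Histone genes of the replication-dependent kind differed between the lines. Of 45 tested, K562 had 36 higher and 1 lower than Hutu-80 (median log2 difference 1.87), 25 higher and 4 lower than HuH-7 (1.22), and 28 higher and 2 lower than U937 (1.54). U937 had 8 higher and 20 lower than HuH-7 (median -0.80) and 11 higher and 4 lower than Hutu-80 (0.18), and HuH-7 had 22 higher and 2 lower than Hutu-80. The class was not tested against other genes in these pairs of lines.

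Of the random assignments of the 12 arrays to 4 groups of 3, only the real one, 1 of 100, set apart as many genes in all 4 contrasts (716, highest other 0); this excludes chance assignment of arrays only and says nothing about reactivity, because arrays of a line are far more alike than arrays of different lines. The same held for the mean contrast, at 1 of 100 (3545, highest other 1030). Within a chip, 10 splits of 6 arrays are too few for a share under 0.05: 1 of 10 gave as many genes as K562 against U937 (4003, highest other 0), and 1 of 10 as many as HuH-7 against Hutu-80 (3972, highest other 0). The 3 ways of splitting the 4 lines into 2 against 2 are too few as well, at 1 of 3 (716, highest other 495). In the mean contrast the other 2 ways called 3202 and 3259 genes, against 3545 for reactivity. A count of that size is therefore not particular to the split by reactivity.

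The first pattern is the set of 716 genes that separate both reactive from both non-reactive lines. A difference between the chips as its whole cause is argued against by the leukocyte markers, since 51.3% of the 39 tested were set apart upward, against 2.36% of 11423 other genes (two-sided Fisher's exact p = 2.69e-22), and 0 downward. The origin of the lines, blood against epithelium, is consistent with 26.5% of 34 epithelial junction and keratin genes being set apart downward, against 3.65% of other genes (two-sided Fisher's exact p = 2.85e-06). For the other 696 genes, PROCR among them, chip and reactivity cannot be told apart, since each chip holds lines of 1 reactivity. Lineage and 2E9 reactivity coincide too, so a gene's place in the set may reflect either, and reactivity itself was not tested.

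The second pattern is that 10 of 82 tested genes for RNAs that mostly lack a poly(A) tail were set apart upward. They were 2 of 3 small nuclear RNAs (RNU11, RN7SK), the only small Cajal body RNA (SCARNA9), 1 of 33 small nucleolar RNAs (SNORD43) and 6 of 45 histones (H1-3, H2BC7, H3C13, H3C14, H4C2 and H4C9). Without RNU11, RN7SK and SCARNA9, which helped to prompt the test, 7 of 79 were set apart upward. The share of other genes was 2.46% (two-sided Fisher's exact p = 0.00358, genes taken as independent). Histones made up 6 of those 7, and U937 had 8 of the 45 histones higher and 20 lower than HuH-7. The p-value therefore does not speak for all RNAs that lack a poly(A) tail. Histones were already part of the pattern when the test was written, after results had been seen. The p-value is thus no independent support for the class. A higher yield of all such RNAs in U937 is argued against by the small nucleolar RNAs, whose median log2 difference was -0.28 in U937 minus Hutu-80 (quartiles -0.70 and -0.03, 33 genes, 1 higher and 4 lower) and 0.25 in U937 minus HuH-7 (7 higher, 2 lower). In K562 their medians of 0.57 over Hutu-80 (7 higher, 0 lower) and 1.27 over HuH-7 (23 higher, 1 lower) are consistent with a higher yield, which stays open there. More dividing cells are argued against by the cell cycle genes, with a median log2 difference of 0.0123 in the mean contrast (quartiles -0.26 and 0.29, 55 genes). A chip effect on these 10 genes cannot be told apart from a difference between the lines, because chip and reactivity coincide, and a biological difference in these RNAs stays open and untested.

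The third pattern is the higher level of intestinal markers in HuH-7, the hepatoma line, than in Hutu-80, the duodenal line; CDX2 stood at 11.92 in HuH-7 and 8.37 in Hutu-80. Swapped labels are argued against, since 96% of the 75 tested hepatocyte and plasma protein genes were higher in the arrays labelled HuH-7. Markers that liver also expresses do not account for the pattern: without the 9 such members, 77.8% of the remaining 18 tested were still higher in HuH-7. An enteroendocrine programme in Hutu-80 stays undecided: of 12 tested enteroendocrine genes other than GCG and CHGB, which prompted the test, 50% were higher in Hutu-80, against 16.7% of all genes, but 4 were higher in HuH-7. The labelled tissues of origin would predict the opposite direction, and no other biological explanation was tested.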
